A study of Homo sapiens with 10 samples.

How the data were processed

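Poly-A RNA of 10 libraries, 2 for each of 5 cell types, was sequenced, per the labels. The submitters' processing notes name TopHat2 2.0.13, Subread 1.5.2, featureCounts and Cufflinks 2.2.1 and the genome build hg19, without the role of each; the scaling between cell types and any filter on rows are not given in the sources used here. The authors deposited 4 tables, 1 per derivative, each with 1 FPKM value for hESC and 1 for the derivative, so the replicates had been pooled or averaged by the authors. The test statistic is a signed score of the comparison with hESC, computed by the authors. The p-value and q-value are also the authors', per the file headers; the lowest p-value in each table is 5e-05, and loci with a p-value of 1 and a score of 0 were taken as not tested. A fold change column was also present and was not used. Coordinates are those of the tables.

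Each table was reduced to the assembled chromosomes, which left out 1190 to 1198 rows on alternative contigs, and of several rows of 1 symbol the row with the highest mean FPKM was kept. Loci that the authors had merged under several symbols (511 to 596 per table) count once as loci and were left out of gene lists. Loci of the Y chromosome and XIST were left out of all counts and lists. Changes are log2(FPKM + 1) of the derivative minus that of hESC. A locus changed where the authors' q-value was below 0.05.

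The deposited FPKM were compared with the deposited statistic. A row was set apart where the ratio of the FPKM and the score had opposite signs, where an FPKM cell held more than 6 significant digits, unlike the rest of the tables, or where, at a mean FPKM of at least 20, the log2 ratio divided by the score was under 0.4 of the table's median. These rules were chosen after seeing the data. A symbol set apart in 1 table was left out of the counts and lists of all 4.

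The tests fixed before the data were examined were limma and camera on libraries. The tables hold 1 value per cell type, so neither could be run, nor could comparisons between derivatives, leave-one-out runs or a blocked fit; the differences have no replicate check here. In their place the authors' q-value is quoted for genes. For 31 gene lists, fixed before the data were examined, the median change of the members with an FPKM of at least 1 in either cell type was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. A gene below that minimum in hESC enters only where it is higher in the derivative, so the direction and percentile of a list with many such genes are set in part by the minimum, and fully for the HOX genes in MESO and NCSC. Lists needed 5 measured members, and a median outside the central 95% is described as standing apart. With 30 or 31 lists per table about 1.5 to 1.55 would do so by chance if members varied independently. Genes regulated together do not, so more could. The placing describes the libraries and is not a test across replicates. Members called are given over all genes (the authors' q-value) and with the authors' p-value adjusted over the list alone by the Benjamini-Hochberg method. The lists covered pluripotency, germ layer and lineage markers, other cell types the cultures could hold, signalling targets, metabolism, proliferation, stress, ribosomal proteins and others. Some lists share genes, such as EOMES in the primitive streak, definitive endoderm and NODAL and activin lists, so lists are not independent. Of their 675 symbols 639 to 644 were found per table, older symbols being matched through a table of gene names; 21 to 26 more lay in merged loci.

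Genes named were, for each comparison, the 5 largest rises and 5 largest falls among loci with q-value below 0.05 and an FPKM of at least 5 in the higher cell type, leaving out loci with locus, clone or open reading frame style names, microRNA and small nucleolar RNA genes, symbols ending in -AS1, XIST and Y-linked genes. To these came up to 4 changed members of each list tied to the culture conditions and up to 2 of each other list that stood apart, or the 2 with the highest mean where none passed, and POU5F1, NANOG, SOX2, MYC and MYCN in each comparison. The part of the rule that asked for libraries not to overlap could not be applied, and not every gene so chosen is printed. NANOG was set apart. Genes named after their values were seen are marked as such; CHCHD2, CAT, MIXL1, T, MESP1, TBX6, SOX10, LEFTY1 and TDGF1 in NPC are also of that kind, as are the copies of POU5F1 and the genes named for the hESC column of the DE table or for opposite signs.

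Alternatives were pseudocounts of 0.1 and 5, quantile normalization of the log2 values, FPKM filters, a minimum log2 change of 1, and others chosen after seeing the data: a filter of 1 FPKM, a pseudocount of 5 for lists, all deposited rows, loci set apart kept, merged loci kept, the deposited score in place of the fold, hESC values from the other 3 tables, and normal p-values from the score with and without centring the fold. The placing of lists was tested on simulated data: of 200 random lists of 20 genes without a shift, 7.5% in DE (12969 genes), 6.0% in MESO (12995), 4.0% in NPC (13051) and 4.5% in NCSC (13012) fell outside the central 95%, after a shift of 0.5 on the log2 scale 97.0%, 75.0%, 47.5% and 59.5% did, and after a shift of 1 100%, 100%, 99.0% and 99.5% did. The genes of the simulated lists were drawn independently, so these shares do not show how often lists of genes regulated together would fall outside. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Read depth is unknown, because FPKM hold no counts, so no counting interval can be given.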

Results

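RNA was sequenced from WA09 cells, an established human embryonic stem cell line (hESC), and from 4 derivatives: definitive endoderm (DE), splanchnic mesoderm (MESO), neural progenitors (NPC) and pre-neural crest cells (NCSC). Each of the 5 cell types had 2 libraries, 10 in all, and the labels do not say whether these came from separate cultures. hESC were grown for 4 days with 4 added factors, FGF at 8 ng/mL, IGF-I at 200 ng/mL, heregulin at 10 ng/mL and activin A at 10 ng/mL. DE was grown for 4 days with FGF at 8 ng/mL and activin A at 100 ng/mL, with Wnt-3a at 25 ng/mL on the first day and without IGF-I or heregulin, so these were withdrawn as well. MESO was grown for 4 days in the hESC factors plus Wnt-3a at 25 ng/mL and BMP-4 at 100 ng/mL. NPC were grown for 6 days without FGF or activin A and with the activin receptor inhibitor SB431542 and the BMP receptor inhibitor LDN at 500 nM. NCSC were grown for 6 days with FGF and without activin A, with SB431542 and BIO, an inhibitor of the kinase GSK3. NPC and NCSC kept IGF-I and heregulin, and were seeded at 90000 cells per square centimetre against 50000 for the others.

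Each derivative had a deposited table with 1 FPKM value per cell type (fragments per kilobase of transcript, scaled to the fragments mapped), the authors' test statistic, p-value and q-value. The replicates had been combined by the authors, so no spread between libraries can be given, and read depth is unknown. Rose, fell and changed refer here to the authors' q below 0.05 in the table of that derivative. Changes are differences of log2(FPKM + 1), which understate the change of low genes. Whether the tables share a scale is not given, and the hESC columns differed between them gene by gene. No test was therefore made across tables, and levels set side by side are descriptive.

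In 13 of 62929 rows with a value in both cell types, the ratio of the deposited FPKM and the deposited test statistic had opposite signs. These 13 rows belonged to 9 genes: GPI, LDHA, PKLR, PKM, PSAT1, SLC2A1, TALDO1, TKT and UGP2, most of them genes of sugar metabolism. Because of this and 2 related checks of the same rows, 18 symbols were set apart, and no direction is given for them. Besides the 9 genes these were HK1, NANOG and 7 small RNAs. A check of sex-linked genes found that the 2 columns of a table did not match in 2 of the 4 tables, so it is not shown that both columns of each table came from 1 line.

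**Figure D1:**
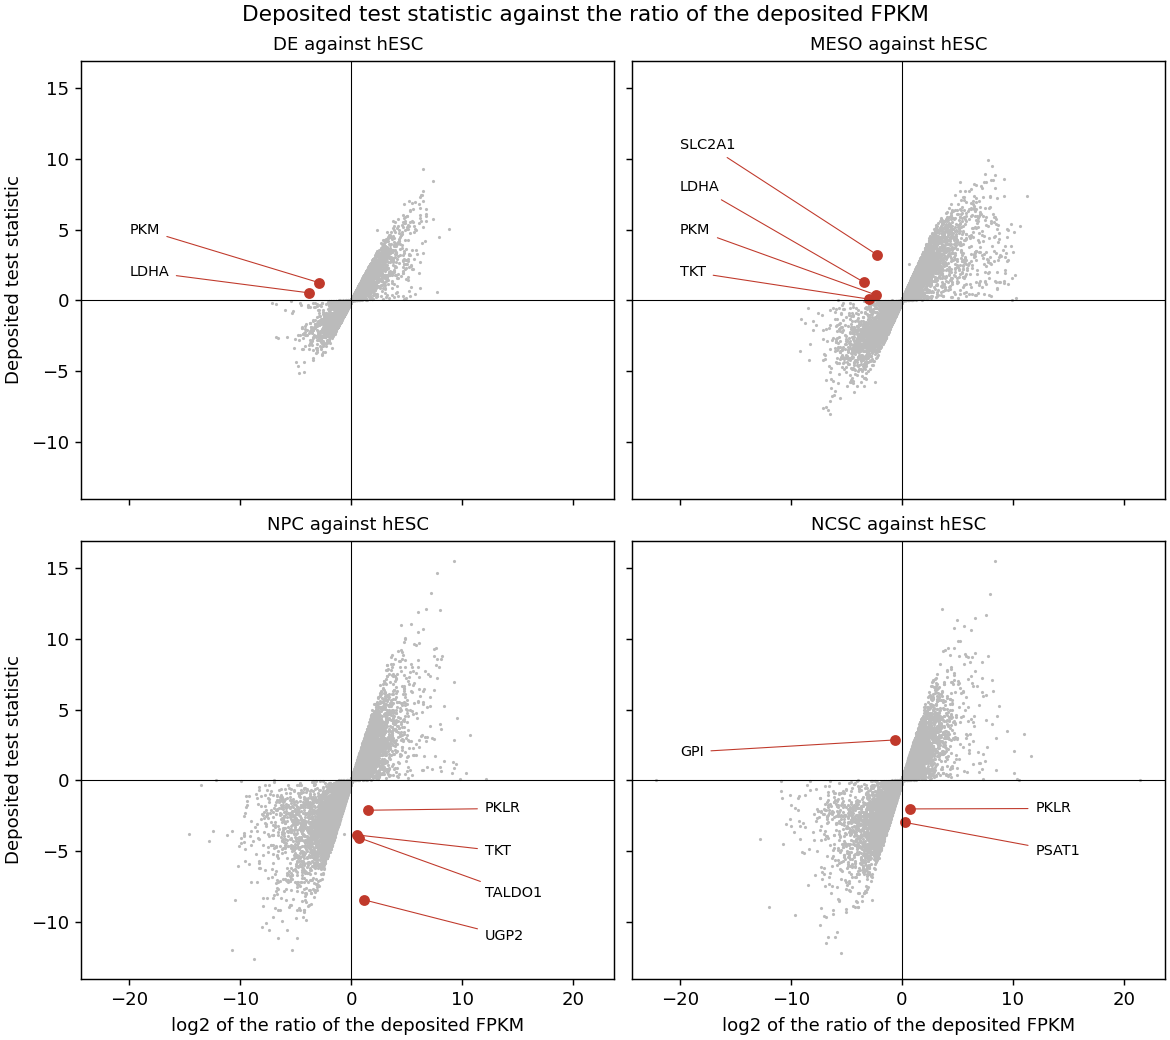
Each panel plots the deposited test statistic against the log2 ratio of the deposited FPKM (derivative over hESC), 1 grey point per locus and 1 red point per row with opposite signs. Grey points lie where ratio and statistic share a sign, and the 13 labelled red points where they differ.

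The DE comparison asked which transcripts differ between hESC and cells driven toward endoderm. By the authors' deposited table, 60 loci rose and 3 fell of 14769 tested. The largest rises were in FGF17, a fibroblast growth factor of the early embryo (8.44 to 916 FPKM), and in a locus merging CER1, a secreted NODAL and WNT antagonist, with ZDHHC21 (32.8 to 2796). CYP26A1, which breaks down retinoic acid, rose from 4.28 to 353, the T-box factor EOMES from 1.85 to 158 and the chemokine receptor CXCR4 from 2.28 to 176. All 5 had q = 0.0186, the lowest value in the authors' deposited table for DE. The locus listed as FGF17 in the DE table spans 21897174 to 21911009 on chromosome 8 (hg19), against 21899778 to 21906319 in the other 3 tables.

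Of 19 measured definitive endoderm genes, 7 rose, none fell and 12 did not pass, and 18 passed when adjusted over the list alone. GATA6 rose from 1.44 to 104 FPKM and SOX17, a transcription factor of endoderm, from 2.71 to 141. The list's median change was 3.77, percentile 100 among matched random lists. Of 11 primitive streak genes 3 rose, among them LHX1 (1.18 to 39.2), and 8 passed when adjusted over the list alone. MIXL1 stood at 1.88 in hESC and 57.4 in DE without passing, with a statistic of 1.55. Its locus in the DE table spans 226410826 to 226497792 on chromosome 1 (hg19), wider than the 226411382 to 226415061 of the MESO table, so its level is uncertain. Of 14 NODAL and activin targets 3 rose, including LEFTY2 (14.3 to 511) and LEFTY1 (25.5 to 682), and 9 passed when adjusted over the list alone.

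None of the 16 WNT targets passed over all genes and 5 did when adjusted over the list alone; AXIN2 was 19.2 in hESC and 26.9 in DE, BAMBI 12.4 and 22.9. Their median change was 0.81, percentile 100. The 13 BMP targets, BAMBI among them, had a median change of 0.83, also percentile 100, although no BMP was added, and none passed either way. Of these 13, 5 were below 1 FPKM in hESC and entered by being higher in DE, which in part set the list's direction. In all 10 were higher and 3 lower, with ID1 at 281 in hESC and 186 in DE and ID3 at 47.1 and 82.4. Of 12 mesenchymal genes 3 rose and 6 passed when adjusted over the list alone, among them the collagen gene COL5A2 (6.10 to 171) and CDH2, N-cadherin (17.9 to 247). Of 17 FGF and ERK targets 1 rose, DUSP4 (1.15 to 53.6), and 5 passed when adjusted over the list alone. Of 13 splanchnic and cardiac mesoderm genes 2 rose, GATA6 and GATA4 (0.846 to 56.1), and 6 passed when adjusted over the list alone; 7 of the 13 were below 1 FPKM in hESC and entered by being higher in DE, and the median lay at percentile 99.5, and at 96.6, within the central 95%, with a pseudocount of 5.

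None of the 22 pluripotency genes passed over all genes, although the list's median change was -1.28, percentile 0, and 8 passed when adjusted over the list alone, 7 of them lower. SOX2, a pluripotency and neural factor, was listed at 238 in hESC and 60.9 in DE (q = 0.239 in the authors' deposited table), and DNMT3B, a DNA methyltransferase, at 834 and 250. POU5F1, the gene of OCT4, was listed at 232 and 29.7, a log2 ratio of -2.97, while 3 near-identical copies in the same table had ratios of -1.10, -1.01 and -1.04. Its ratio divided by its statistic was 2.08. The median of this quotient over loci of the DE table with a mean FPKM of at least 20 was 0.71. The level of POU5F1 in DE is therefore given as uncertain. In MESO the ratios of POU5F1 (-3.45) and its copies (-3.40, -3.40 and -3.54) lay close together, and in NCSC too (-3.69, and -3.54, -3.36 and -3.65). MYC was 27.0 and 19.7 and MYCN 33.3 and 17.2. The 3 loci that fell, named after their values were seen, were LOC100506013 (45.0 to 2.31), C5orf47 (0.912 to a listed 0) and KCNK9 (0.691 to a listed 0); over loci with at least 1 FPKM in either cell type, an alternative chosen after seeing the data, 1 fell. Normal p-values computed from the deposited statistic, an alternative chosen after seeing the data, called 180 loci in place of 63, with 161 higher and 19 lower, and 151 higher and 20 lower with the fold centred on the median of all genes.

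The MESO comparison asked the same of cells given BMP-4 and Wnt-3a. By the authors' deposited table, 1337 loci rose and 791 fell of 14774 tested. HAND1, a transcription factor of lateral mesoderm and extraembryonic tissue, rose from 1.27 to 758 FPKM (chromosome 5, 153854531 to 153857824, hg19; q = 0.000868 in the authors' deposited table). EPAS1, a hypoxia-inducible factor subunit, rose from 0.964 to 316, COL3A1 from 0.289 to 202, IGFBP3 from 3.65 to 620 and GABRP from 1.18 to 230. SOX2 fell from 231 to 1.97, TDGF1, a NODAL co-receptor, from 253 to 2.55, and the noncoding RNA ESRG from 247 to 2.72. SNAR-C4 and SNAR-B1, members of a family of near-identical small RNAs whose reads cannot be separated with confidence, also fell and were listed at 0 in MESO.

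Of 23 splanchnic and cardiac mesoderm genes 18 rose, none fell and 5 did not pass, and 20 passed when adjusted over the list alone. TBX3 rose from 0.354 to 98.2 FPKM and GATA4 from 0.549 to 49.3; the list's median change was 2.91, percentile 100. Of the 23 genes 17 were below 1 FPKM in hESC and so entered by being higher in MESO, while 3 were left out as below 1 in both cell types, of which 1 rose and none fell. Of 17 BMP targets 15 rose, including GATA3 (0.383 to 114) and MSX2 (1.02 to 147), and 16 passed when adjusted over the list alone. Of 16 WNT targets 9 rose, among them BAMBI (13.3 to 509), LEF1 (0.315 to 24.8), TNFRSF19 (0.556 to 29.4) and DKK1 (1.36 to 21.3), and 11 passed when adjusted over the list alone. BAMBI is also in the BMP list, and BMP-4 and Wnt-3a were both added, so its rise cannot be assigned to either. HAND1 and TBX3 are in the BMP and mesoderm lists, and MSX2 is in the BMP and neural crest and border lists.

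Markers of other tissues moved in the same table. Of 16 trophoblast and amnion genes 10 rose and none fell, with a median change of 4.41, percentile 100, and 10 passed when adjusted over the list alone; 11 of the 16 were below 1 FPKM in hESC and entered by being higher in MESO, and none of the 3 left out changed. Named after their values were seen, CGA, a subunit of chorionic gonadotropin, rose from a listed 0 to 95.3 FPKM, VTCN1 from 0.0414 to 44.9, and the keratins KRT8 from 89.4 to 987 and KRT18 from 80.0 to 712. Of 11 fibroblast genes 8 rose and 9 passed when adjusted over the list alone, including COL6A3 (0.354 to 91.9). Of 22 neural crest and border genes 14 rose and 3 fell, SNAI2 rose from 0.243 to 80.9, and 17 passed when adjusted over the list alone. Of 17 mesenchymal genes, 3 of them shared with the neural crest and border list and 3 with the fibroblast list, 14 rose and none fell, and 14 passed when adjusted over the list alone. Of 10 endothelial and blood genes 6 rose, including GATA2 (1.60 to 89.1), and the same number passed when adjusted over the list alone.

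Of 13 primitive streak genes 2 rose, EVX1 (0.0631 to 9.25) and SP5 (1.01 to 5.54), NODAL fell (11.4 to 0.947) and 10 did not pass; 6 passed when adjusted over the list alone. The nascent mesoderm factors T (0.579 in hESC and 3.09 in MESO), MESP1 (0.220 and 1.32) and TBX6 (3.13 and 2.04) did not pass. Of 14 NODAL and activin targets 5 fell and 2 rose, and 9 passed when adjusted over the list alone. Of 22 pluripotency genes 16 fell and none rose, and 18 passed when adjusted over the list alone; PRDM14 fell from 69.6 to 0.843, USP44 from 65.2 to 0.716 and POU5F1 from 217 to 19.9. MYC was 34.4 in hESC and 25.7 in MESO (q = 0.588 in the authors' deposited table) and MYCN 41.4 and 17.6 (q = 0.0556 in the authors' deposited table). Normal p-values computed from the deposited statistic called 1153 loci in place of 2128.

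**Figure D2:**
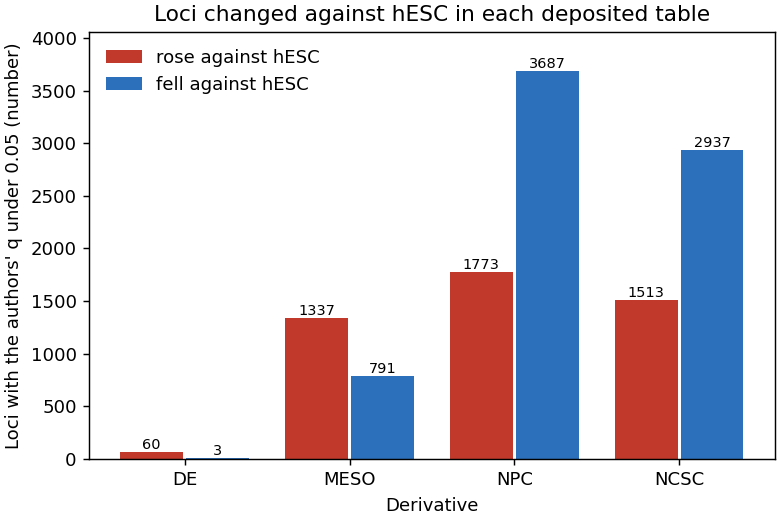
Bars give the number of loci with the authors' q under 0.05 that rose (red) or fell (blue) against hESC in each deposited table. DE has 60 and 3, MESO 1337 and 791, NPC 1773 and 3687, and NCSC 1513 and 2937.

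The NPC comparison asked which transcripts differ in neural progenitors. By the authors' deposited table, 1773 loci rose and 3687 fell of 14838 tested, and the median change of all expressed genes was -0.27; list medians below are relative to it. DLK1, a NOTCH pathway ligand homolog, rose from 2.40 to 1485 FPKM (chromosome 14, 101193201 to 101201467, hg19; q = 0.000323 in the authors' deposited table). IGFBP5 rose from 0.87 to 181, SMOC1 from 0.448 to 114, PRSS23 from 1.31 to 140 and PRTG from 0.665 to 96.4. ESRG fell from 283 to 0.163, SPP1, osteopontin, from 346 to 0.799, POU5F1 from 235 to 0.645, GAL, galanin, from 132 to 0.243 and CDH1, E-cadherin, from 89.6 to 0.0631. The level of POU5F1 in NPC is given as uncertain as in DE. Its log2 ratio was -8.51 and those of its copies -6.81, -6.64 and -7.51. Its ratio divided by its statistic was 2.74. The median of this quotient over loci of the NPC table with a mean FPKM of at least 20 was 0.43. For the copy POU5F1P4 this quotient was 6.14 in NPC, 2.16 in MESO and 2.01 in NCSC. Other named genes also had small statistics beside their ratios, such as COL3A1 in MESO (699-fold, 2.75) and PAX3 in NCSC (1102-fold, 2.03). Their folds and levels are uncertain too, and COL3A1 and PAX3 were near 0 in hESC (0.289 and 0.0169 FPKM).

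Of 25 neural progenitor genes 20 rose, none fell and 5 did not pass, and 24 passed when adjusted over the list alone; 14 of the 25 were below 1 FPKM in hESC and entered by being higher in NPC, and the 1 left out also rose. The transcription factors SIX3 and PAX6 rose from 0.196 to 54.9 and from 0.349 to 38.1 FPKM, and HES5, a NOTCH target, from 0.22 to 50.9. The eye field gene RAX (0.156 to 30.1), named after its value was seen, also rose. Of 10 neuronal genes 3 rose, including MAP2 (0.732 to 42.1), and 4 fell, including TUBB3 (137 to 37.5) and GAP43 (10.6 to 2.15); 7 passed when adjusted over the list alone and the median lay at percentile 90.4. SOX2 rose from 260 to 418. Of 15 mesenchymal genes 9 rose, including ZEB2 (0.204 to 17.6), and 2 fell, and 12 passed when adjusted over the list alone. Of 17 neural crest and border genes, 2 of them shared with the mesenchymal list, 8 rose and 4 fell, and 13 passed when adjusted over the list alone; the median lay at percentile 100, but at 85.0 with the deposited statistic in place of the fold. CHCHD2, a mitochondrial protein gene, and CAT, the catalase gene, rose beside these groups from 0.315 to 20.4 and from 0.0979 to 17.4 FPKM, in cells cultured for 6 days against 4 for hESC, and in a set of 4 tables of which 2 did not match in sex-linked genes.

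Of 14 NODAL and activin targets 6 fell and none rose, with a median change of -3.04, percentile 0; SKIL fell from 50.1 to 3.96, NODAL had a log2 change of -3.12, and 10 passed when adjusted over the list alone. LEFTY1 was 20.3 in hESC and 0.0626 in NPC without passing (q = 0.0795 in the authors' deposited table). Of 12 BMP targets 5 fell, including ID1 (265 to 15.2) and SMAD7 (8.21 to 0.71), 2 rose, including ID2 (18.7 to 65.3), and 8 passed when adjusted over the list alone; the BMP list's median lay at percentile 0.87, but at 15.1 with a pseudocount of 5 and at 8.17 with the hESC values of the other 3 tables. Of 22 pluripotency genes 16 fell, among them PRDM14 (78.7 to 0.575), SOX2 rose, and 17 passed when adjusted over the list alone. TDGF1, listed at 297 in hESC and 0.0117 in NPC, did not pass (q = 0.350 in the authors' deposited table).

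Of 21 epithelial junction genes 17 fell and none rose, including ESRP1 (90.3 to 0.444), and 17 passed when adjusted over the list alone. Of 71 oxidative phosphorylation genes 38 fell and none rose, including ATP5G1 (153 to 16.9), and 45 passed when adjusted over the list alone. The median of -0.62 lay at percentile 0.33. Before centring it was -0.89, beside a middle of -0.61 for random lists matched in expression, so part of the fall was general to such genes. Of 25 TCA cycle genes 14 fell and none rose, including IDH3A (27.2 to 3.08), and 17 passed when adjusted over the list alone. Of 19 hypoxia and HIF targets 10 rose and 1 fell, with DDIT4 at 64.3 in hESC and 239 in NPC, and 11 passed when adjusted over the list alone. MYC fell from 38.4 to 11.3 and MYCN from 45.3 to 10.3. With folds centred on the median of all genes and normal p-values, 1386 loci were higher and 1593 lower, beside 1773 and 3687 as deposited; without the centring 1022 were higher and 2259 lower, 3281 in all.

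The NCSC comparison asked the same of cells given SB431542 and BIO. By the authors' deposited table, 1513 loci rose and 2937 fell of 14881 tested, and the median change of all expressed genes was -0.23. DLK1 rose from 2.27 to 545 FPKM, IGFBP5 from 0.813 to 268, the WNT target SP5 from 0.885 to 82.0, CNTFR, a cytokine receptor, from 0.713 to 69.7 and GREB1L from 0.355 to 52.5. The locus listed as SP5 in the NCSC table spans 171556888 to 171579291 on chromosome 2 (hg19; q = 0.000455 in the authors' deposited table), a wider span than the 171571856 to 171574498 of the other 3 tables. ESRG fell from 265 to 2.25, ESRP1, a splicing factor of epithelia, from 85.3 to 0.5, and DPPA5 from 73.8 to a listed 0, as did SNAR-C3 and SNAR-B1, from 66.2 and 65.5.

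Of 18 neural crest and border genes 10 rose, 4 fell and 4 did not pass, and 14 passed when adjusted over the list alone. Of the 18, 6 were below 1 FPKM in hESC and entered by being higher in NCSC. Another 9 of the 27 listed were left out as below 1 in both cell types, of which 1 rose and 0 fell. PAX3, a neural fold and crest factor, rose from 0.0169 to 18.6 FPKM, SNAI2 from 0.286 to 11.7, GBX2 from 0.897 to 13.6 and, named after its value was seen, SOX9 from 2.72 to 16.1. FOXD3 fell from 10.7 to a listed 0, and SOX10 was 2.57 in hESC and 2.91 in NCSC. Named after their values were seen, TFAP2A (0.289 in hESC and 0.0463 in NCSC) and PAX7 (0.0537 and 0.0512) were below 1 FPKM in both. Markers of other cell types moved beside them. Of 7 fibroblast genes 5 rose, including COL1A2 (22.9 to 413) and PDGFRB (1.55 to 13.8), 1 fell, and 7 passed when adjusted over the list alone. Of 15 mesenchymal genes 11 rose, including ZEB2 (0.175 to 21.6), 1 fell, and 12 passed when adjusted over the list alone; 2 of the 15 are also in the neural crest and border list and 1 in the fibroblast list. Relative to the median of all genes, the median change was 1.16 for the neural crest and border list, at percentile 100. It was 2.09 for both the fibroblast and the mesenchymal list, also at percentile 100. These lists share 1 gene, so their equal medians are not separate results. Of 16 WNT targets 8 rose, including TNFRSF19 (0.613 to 37.1), LEF1 (0.346 to 24.6) and NKD1 (1.04 to 27.3), 2 fell, and 12 passed when adjusted over the list alone. CHCHD2 and CAT rose beside these groups from 0.303 to 45.1 and from 0.147 to 22.9 FPKM, with the same difference in days of culture and the same 2 of 4 tables not matching in sex-linked genes.

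Of 39 listed HOX genes 32 lay in the table as single loci, and 24 of these were below 1 FPKM in both cell types, of which 1 rose and none fell. The other 8 were all below 1 FPKM in hESC and entered only by being higher in NCSC, so the list's direction was set by that minimum; 5 of them rose, among them HOXB9 (0.0761 to 21.5), HOXB1 (0.48 to 26.9) and HOXB2 (0.139 to 20.3), and 6 passed when adjusted over the list alone. CRABP1, a retinoic acid binding protein, rose from 105 to 2670. Of 14 neural progenitor genes 8 rose, including ZIC2 (13.7 to 123) and SOX1 (0.284 to 9.56), and 2 fell, including OTX2 (22.5 to 0.0376), a fore- and midbrain factor; 12 passed when adjusted over the list alone. Of 22 pluripotency genes 16 fell and none rose, and 20 passed when adjusted over the list alone; L1TD1 fell from 186 to 4.13, LCK from 21.1 to 0.0941 and POU5F1 from 221 to 17.1. SOX2 was 244 in hESC and 167 in NCSC (q = 0.120 in the authors' deposited table).

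Of 25 proliferation genes 19 fell, including MCM5 (119 to 20.6) and MCM6 (82.3 to 20.9), 1 rose, and 22 passed when adjusted over the list alone. MYC fell from 36.3 to 3.39, and MYCN fell with a log2 change of -0.81. Of 17 glycolysis and lactate genes that were not set apart 6 rose and 1 fell, and 7 passed when adjusted over the list alone; SLC16A3, a lactate transporter, rose from 19.7 to 80.5 and SLC2A3, a glucose transporter, from 195 to 614. Of 21 hypoxia and HIF targets 14 rose and 1 fell, with NDRG1 at 2.55 in hESC and 81.8 in NCSC, and 16 passed when adjusted over the list alone. Of 21 epithelial junction genes 17 fell and 1 rose, and 18 passed when adjusted over the list alone. With folds centred on the median of all genes and normal p-values, 1026 loci were higher and 1124 lower, beside 1513 and 2937 as deposited; without the centring 787 were higher and 1554 lower, 2341 in all. Asking for a log2 change of at least 1 as well as q left 2872.

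**Figure D3:**
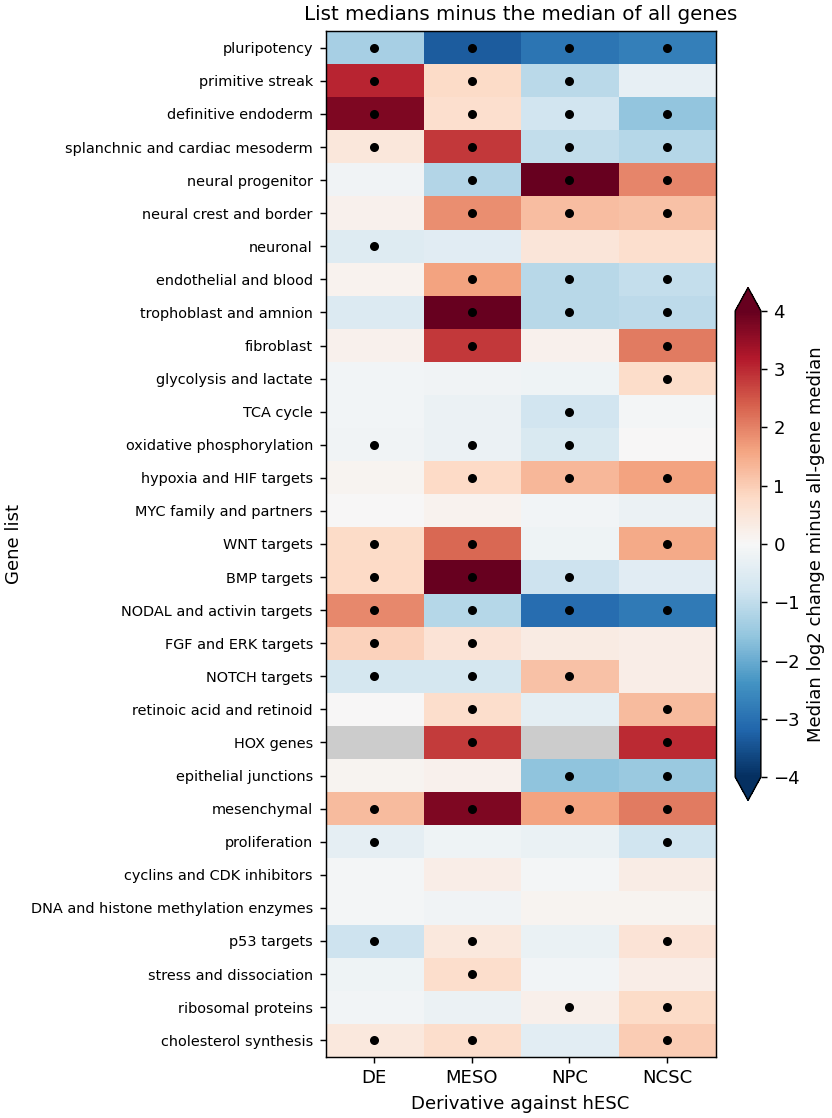
Colour gives the median log2 change of each gene list minus the median of all expressed genes, by derivative, and a black dot marks a median outside the central 95% of 10000 matched random lists. Dots mark 15 lists in DE, 22 in MESO, 17 in NPC and 20 in NCSC; grey cells had too few measured members.

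Marker levels set side by side from the 4 tables, which may not share a scale, differed by derivative, without a test of those differences. SOX17 was 141 FPKM in DE, 2.08 in MESO and a listed 0 in NPC and NCSC. HAND1 was 758 in MESO and 0.646 in DE, and GATA4 was 56.1 in DE and 49.3 in MESO. PAX6 was 38.1 in NPC and 0.348 in NCSC, SIX3 54.9 and 0.0415, and PAX3 1.87 and 18.6. The 4 hESC values of SOX2 ran from 231 to 260 and those of POU5F1 from 217 to 235. Markers low in hESC varied more in proportion. Their hESC values ran from 0.142 to 1.47 for HAND1, 0.858 to 2.40 for DLK1, 1.24 to 2.71 for SOX17 and 0.943 to 1.85 for EOMES.

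**Figure D4:**
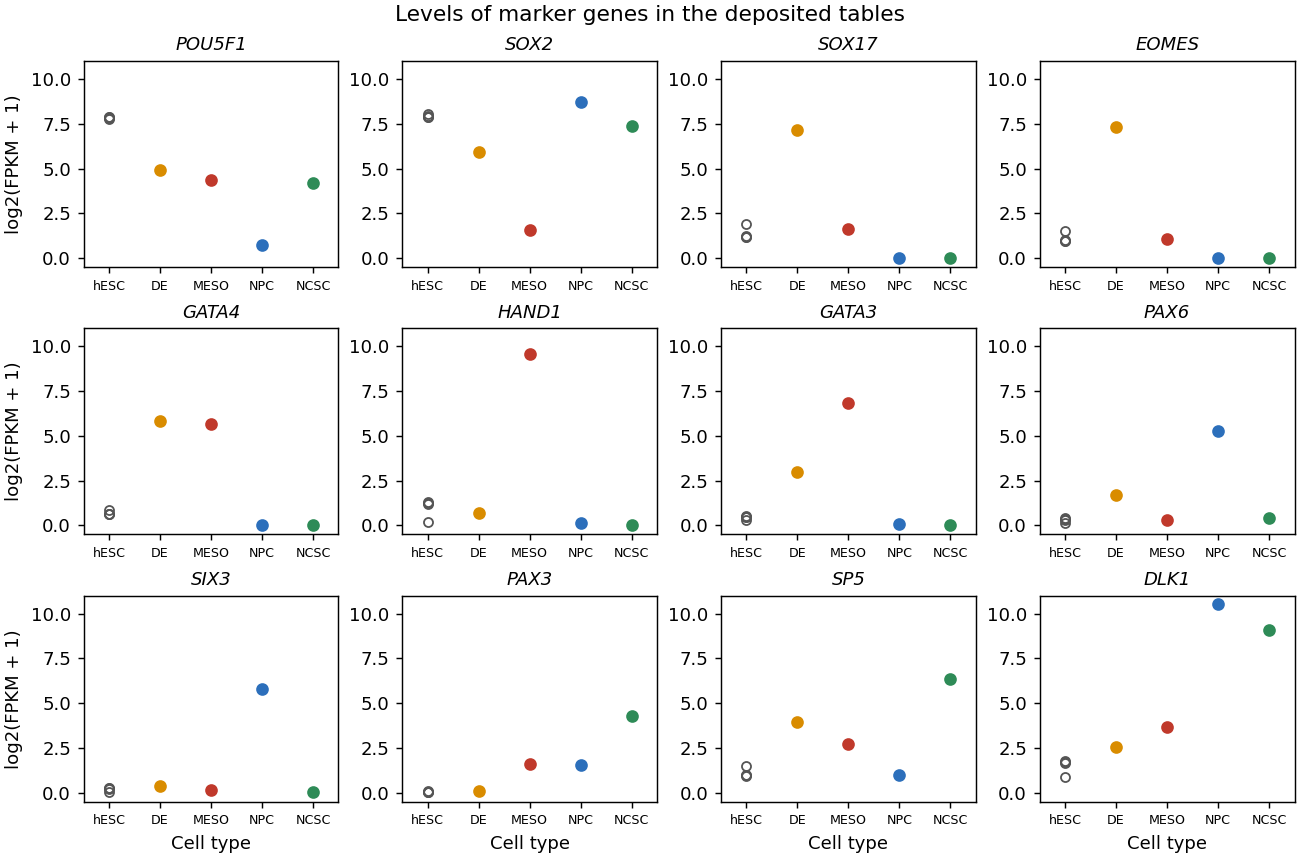
Each panel plots log2(FPKM + 1) of 1 gene by cell type, with open circles for the hESC columns of the 4 tables and 1 filled circle per derivative. The tables may not share a scale. SOX17 and EOMES are highest in DE, HAND1 and GATA3 in MESO, PAX6, SIX3 and DLK1 in NPC, and PAX3 and SP5 in NCSC.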

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

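No paired analysis was possible because each table holds 1 value per cell type, with no value per replicate. For the same reason the planned leave-one-out runs, the joint fit, the fit without a mean-variance trend, the estimated correlation and the rotation test were not run, nor were the comparisons between derivatives; pseudocounts, quantile normalization and median of ratios scaling could not be applied to the authors' q-values. The alternatives that use the deposited statistic, centre the fold, keep sets of loci, replace hESC values, filter at 1 FPKM or add a pseudocount of 5 for lists were chosen after seeing the data.

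Counts of loci stayed within 1.5 times the reported count without a filter, with FPKM of at least 1 or 5, over all deposited rows and with the loci set apart kept. A minimum log2 change of 1 left 2872 loci in NCSC in place of 4450 and 3649 in NPC in place of 5460, by construction. Only the NCSC count moved beyond 1.5 times, and that of NPC lay just inside this limit. Normal p-values from the deposited statistic gave 180 loci in DE, 1153 in MESO, 3281 in NPC and 2341 in NCSC, and with the fold centred on the median of all genes 171, 1175, 2979 and 2150; the cause was not tested. The number of lists standing apart stayed within 1.5 times the reported number under all 7 alternatives run for lists, and none of those standing apart moved to the other side under these. Centring on the median of all genes turned the sign of 5 list medians, of which 1 stood apart, ribosomal proteins in NPC (-0.07 to 0.20); another was oxidative phosphorylation in NCSC (-0.21 to 0.02). Named genes were run under 3 alternatives, pseudocounts of 0.1 and 5 and the centred fold, and no called one reversed. A pseudocount cannot turn the sign of a single gene, and centring subtracted only -0.27 to 0.07. This outcome was therefore nearly fixed in advance and is no check of stability. With the loci set apart kept, the glycolysis and lactate list stood apart in DE (median -0.25, percentile 0.26) and in MESO (-0.35, percentile 0.06), and without them in neither (-0.06 and -0.08). With a pseudocount of 5, 10 lists no longer stood apart and 2 came to, the former including BMP targets in NPC and splanchnic and cardiac mesoderm in DE. With hESC values of the other 3 tables, 6 lists came to stand apart and 4 no longer did, BMP targets in NPC among the latter. Most of those added were in DE, whose hESC column deviated, with 19 lists standing apart in place of 15. Stress and dissociation and ribosomal proteins were among them. Unknown depth limits what can be said of genes listed at or near 0.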

Other observations

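The tests of opposite signs, of CHCHD2 and CAT, of gene models and of other hESC libraries were chosen only after the result was seen, and that of endoderm cells in the hESC libraries before. Gene groups not yet described, or described only for other derivatives, had these counts by the authors' deposited table. Oxidative phosphorylation also stood apart downward in DE (median -0.10, percentile 0.295) and MESO (-0.18, percentile 0.12). None of its 71 and 70 genes passed, also over the list alone, and in DE the percentile was 4.24 with merged loci kept. Of 21 hypoxia and HIF targets 6 rose in MESO and 0 fell, percentile 99.99, and 10 passed when adjusted over the list alone. Of 19 cholesterol synthesis genes 7 rose in NCSC and none fell, including STARD4 (30.1 to 129 FPKM) and INSIG1 (51.0 to 216), and 2 rose in MESO, MVK (10.9 to 35.9) and MVD (65.3 to 175); 10 and 2 passed when adjusted over the list alone. Of 46 ribosomal protein genes 8 rose in NCSC, among them RPL6 (161 to 292) and RPS23 (144 to 252), and 3 fell in NPC, and none passed in either when adjusted over the list alone. Their NPC median change was -0.07 as deposited and 0.20 relative to all genes, a sign that turns with the centring, and reads shared with pseudogenes make these levels uncertain. Of 19 p53 targets 4 rose in MESO and none fell, and 7 rose and 2 fell in NCSC, with GDF15 at 7.39 and 51.0 in MESO and 6.84 and 53.4 in NCSC (hESC first); 4 and 11 passed when adjusted over the list alone. The MESO median of the p53 targets lay at percentile 98.6, but within the central 95% with a pseudocount of 5 (96.6), with merged loci kept (96.4) and with the hESC values of the other 3 tables (86.7). Of 20 stress and dissociation genes 7 rose in MESO and none fell, and 9 passed when adjusted over the list alone. The 19 p53 targets of the DE table had a median change of -0.78, percentile 0, and none passed over all genes and 1 when adjusted over the list alone.

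Of 15 NOTCH targets 10 rose and 4 fell in NPC, with DLL1 at 5.29 in hESC and 99.6 in NPC, and 14 passed when adjusted over the list alone. In MESO 4 of 13 fell, among them NRARP (21.8 to 3.03), and 2 rose, among them HEY1 (0.626 to 33.7), and 8 passed when adjusted over the list alone. Of 173 loci with a log2 change of at least 3 in DE, 46 passed, beside 298 of 389 in MESO. Over loci with a mean FPKM of at least 20, the median log2 ratio divided by the statistic was 0.71 in DE and 0.43 in NPC.

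The first pattern is the 13 rows whose FPKM ratio and statistic had opposite signs, 6 of them with q below 0.05 in the authors' deposited table; for example TKT in NPC was listed at 442 and 621 FPKM with a statistic of -3.87, and SLC2A1 in MESO at 41.5 and 8.92 with 3.21. Ratios too close to 1 for a certain sign are argued against by a median absolute log2 ratio of 1.47 in these rows. Estimation over many isoforms in any kind of gene stays open, since the tables used here count no isoforms; 6 of the 13 rows, in 4 genes, lie in the glycolysis list, which does not bear on it. Derivative values entered separately from the test output may account for the 5 rows with extra digits, all in NPC and NCSC: more than 6 significant digits stood in 13 derivative cells and 0 hESC cells, and chance would put 0.00269 of the former in these rows. For the 8 rows without extra digits, which include those of DE and MESO, separate entry stays open. Of their genes, LDHA, PKM, TKT and PKLR had extra digits in a derivative cell of another table, while GPI and SLC2A1 had none in any. Extra digits also stood in the derivative cells of NANOG in DE and UGP2 in MESO, where the signs were not opposite. No biological explanation was tested for any of the 13.

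The second pattern is that CHCHD2 and CAT were below 0.6 FPKM in hESC, DE and MESO and rose in NPC and NCSC. A mislabelled sample or libraries of another line or stock may account for it: the columns did not match in sex-linked genes in 2 of the 4 tables, where 1 line throughout would have given 0 unless cells of it had changed in culture, which stays open. Regulation in the course of neural differentiation stays open as well, since the ratio of CHCHD2 to hESC, at least 64.7 in both, is what either would give. Of 21271 loci 9 were below 0.6 FPKM in hESC, DE and MESO and at least 5 in NPC and NCSC, these 2 and the neural factors SOX1 and POU3F2 among them, and 26 were the reverse, the epithelial genes ESRP1 and CLDN7 among them; with limits set after the values were seen, the tally does not separate the explanations. Until this is settled, changes in NPC and NCSC may hold differences between lines as well as between cell types.

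The third pattern is that the hESC column of the DE table differed from those of the other 3 tables, with MT1G at 17.2 FPKM in place of 129 to 151, ASS1 at 18.3 in place of 61.5 to 70.3 and CDKN1A at 66.8 in place of 33.0 to 34.6. Gene models that differ between tables are argued against, as the robust SD of the log2 deviation was 0.276 at loci with the same coordinates in all 4 tables and 0.236 at the others. As the source of the deviation over all loci, endoderm cells in those hESC libraries are argued against too. The median share of DE cells estimated from the genes that rose, 0.578%, would give a robust SD of 0.0033 in place of 0.245. The presence of such cells is not excluded, since a robust SD hardly responds to a minority of genes. Of the 56 genes used 37 gave a share above 0, with quartiles of -0.104% and 1.29%. Other hESC libraries, or other weights of the same ones, may account for the 0.245, which exceeds the highest of the other 3 tables (0.113), and these cannot be told apart because the columns are pooled.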
